A study of Homo sapiens with 6 samples.

How the data were processed

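HCT116 cells, a human colon carcinoma line grown in medium with 10% serum, were transfected for 24 h with 4 pmol of a control oligonucleotide or a mir-493 mimic. Total RNA was taken from 3 independent experiments for each, per the labels. Cy3-labelled RNA made from 0.2 ug of each sample was put on a 1-colour Agilent array, per the labels' protocols. Samples were grouped by their titles into control and mir-493, with 3 arrays each.

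The arrays were read with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. The deposited scanner files give an intensity for each spot. The processed signal is background-subtracted within the array and is not scaled between arrays. A deposited table of the whole series holds, as a check against the scanner files showed, a linear ratio. Each value is the array's processed signal divided by that array's 75th percentile. The check took the 8527 to 8532 probes on an array with a ratio above 1, and between 99.84% and 99.95% of these agreed within 1%. Dimmer probes were not compared. Scale and centring of the table were thus settled on the brighter probes. Each column holds 1 sample, so it has no direction to settle. The column medians were 0.086 for each control array and 0.093, 0.097 and 0.095 for the mir-493 arrays. Which program scaled those ratios is not given in the sources used here.

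The main values were computed from the scanner files in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Control spots and spots marked as outliers (223 to 318 spots that were not controls on an array) were left out, and spots of one probe were averaged. The log2 of the processed signal was then taken, minus the array's 75th percentile over probes that were not controls, which lay between 1461 and 1581 signal units. Of 34127 probes, 24110 were tested because they were well above background on all arrays of at least 1 group and had an unmarked spot on every array. There were 21 probes without such a spot. A probe's gene was named by matching its RefSeq accession, without version, to a table of genes of the assembly GRCh38.p14. This named 24910 probes, none with several genes, and left 9217 unnamed. The file headers give the build hg19, so the table served for names only and no positions are given. A gene was represented by its brightest tested probe over the 6 arrays. Of 3574 genes with 2 or more tested probes, 204 (5.71%) had probes past the threshold in opposite directions.

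Groups were compared with limma (lmFit and eBayes, two-sided) over all 6 arrays with no covariate, and p was adjusted by Benjamini-Hochberg over all tested probes with a threshold of 0.05. Over probes, 15770 of 24110 passed. Where no array of the dimmer group was well above background, the change is given as a bound. It sets the brighter group's mean against the dimmer group's mean of, for each array, the higher of the probe's own signal and the lowest signal among probes well above background. The same limma fit gives the adjusted p. A bound holds for the processed signal as the scanner software subtracts its background, and normexp with its added offset gave values below the bounds. The smallest two-sided p that an exact permutation test of 3 against 3 arrays can give is 0.1, so no such test was used for single genes. Gene lists were compared with the other genes by camera with the preset correlation of 0.01, adjusted over 18 lists, and again with a correlation estimated from the data; fry was run beside it. Each list median was also set against the medians of 10000 random lists of the same size matched on mean level. A list's members not tested here are left out of its counts. IGF1R, MAP2K7, E2F1, MAD2L1, DKK1, FOS, FOSL1, ATF3, BBC3, BAX, SESN2, BIRC5 and MYC each stand in 2 lists.

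The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, IGF1R and MAP2K7, and up to 4 members of each list with the largest change past the threshold. Genes with no control or no mir-493 array well above background are given as bounds, and those whose bound was at least as large as the smallest of the 12 rises or falls are named with them. Some genes that the rule took are not reported here. Other genes named were chosen after their values were seen. These are FZD4, RHOC and TPI1 in the report and the members of gene families at the end.

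The steps were tested on simulated arrays of the same 14697 genes, with 200 genes changed by known amounts. Limma recovered 20 of 50 genes changed by 0.25 on the log2 scale and 41 of 50 changed by 0.5. It recovered 50 of 50 changed by 1 and 50 of 50 changed by 2, and it called 7 unchanged genes. The simulated noise was independent between genes, and far fewer genes were changed than the 10209 called in the data. These rates therefore need not hold for the data. Pearson's r between arrays, across genes, was 0.9986 to 0.9988 within control, 0.9982 to 0.999 within mir-493 and 0.9824 to 0.9842 between the groups; genes are not independent replicates.

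The alternatives tried were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, median centring, the deposited ratio table, no filter on dim probes, only probes well above background on all 6 arrays, the mean over a gene's probes, the replicate number as a block, the slide as a block, eBayes with trend and robust, leaving out each array in turn, stricter thresholds and camera's estimated correlation. A threshold of a 1.5-fold change (limma treat) and slide 1 alone were added after the data were seen. Normexp was planned on the mean spot signal and was run on the median spot signal with the median background signal, the columns used here. Sites for the microRNA's seed in 3′ untranslated regions, planned for both arms, were not analysed here because no such sequence was used. Figures were drawn with matplotlib 3.10.9.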

Results

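Gene expression was measured in HCT116 cells, a human colon carcinoma line, that had been transfected for 24 h with 4 pmol of either a control oligonucleotide or a mimic of the microRNA mir-493. A mimic is a synthetic RNA that is meant to act in place of the cell's own microRNA. The labels do not say which of the 2 arms of mir-493 it carried. Each transfection was measured on 3 arrays, 1 for each of the experiments that the series' design text calls independent, and each of the 6 samples had its own 1-colour array of total RNA. Each array held 43118 spots that were not controls, of which 70.1% to 74.9% were well above background, and no spot was saturated. The number of arrays limits the precision of every value below. Log2 folds are mir-493 over control with their standard error (SE) from limma, and n = 3 arrays in each group throughout. The level of the microRNA itself was not analysed here.

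The comparison asked how mir-493 changed gene expression, as the series title puts it. IGF1R, the receptor for insulin-like growth factors, fell by 1.11 on the log2 scale (SE 0.061), and MAP2K7, a kinase that activates JNK, fell by 0.69 (SE 0.043). Of 22 p53 targets 18 rose and 2 fell (median log2 fold 0.90), and of 20 interferon response genes 16 rose and 1 fell (median 0.87). Of 25 genes of S phase and DNA replication 21 fell and 1 rose (median -0.35), and of 20 genes of cholesterol synthesis 15 rose and 2 fell (median 0.32, or 0.17 with median centring). Each of these lists passed camera with its preset correlation and lost the call with an estimated one, at an adjusted p of 0.429 with an estimated correlation for S phase and 0.585 for the other lists.

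Of the 14697 genes tested, 10209 (69.5%) passed an adjusted p of 0.05 in limma, 5607 of them higher and 4602 lower after mir-493. At least 2-fold changes were fewer, with 797 genes higher and 310 lower. Changes of 4-fold or more were found for 156 genes that rose and 22 that fell. These counts take the measured fold even where only a bound holds. Of the genes tested, 213 had no control array well above background and 7 no mir-493 array. With only probes well above background on all 6 arrays, 566 genes were at least 2-fold higher and 302 lower. The counts at 2-fold depended on the scaling, with 301 genes higher and 217 lower with normexp background correction and quantile normalization, 643 and 350 with quantile normalization alone, and 616 and 499 with median centring. All 3 values of one group lay above all 3 of the other for 11153 genes, where chance gives 10% of the genes. The typical SD between arrays was small, with a median over genes of 0.045 (log2) in control and 0.055 in mir-493, so many of the calls were small changes. How many of such small changes were called in each direction depended on the scaling. Centring each array on its median moved every log2 fold by -0.145 and gave 3665 genes higher and 6400 lower; 8267 of the called genes then passed the threshold in their former direction and 0 in the opposite one.

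**Figure D1:**
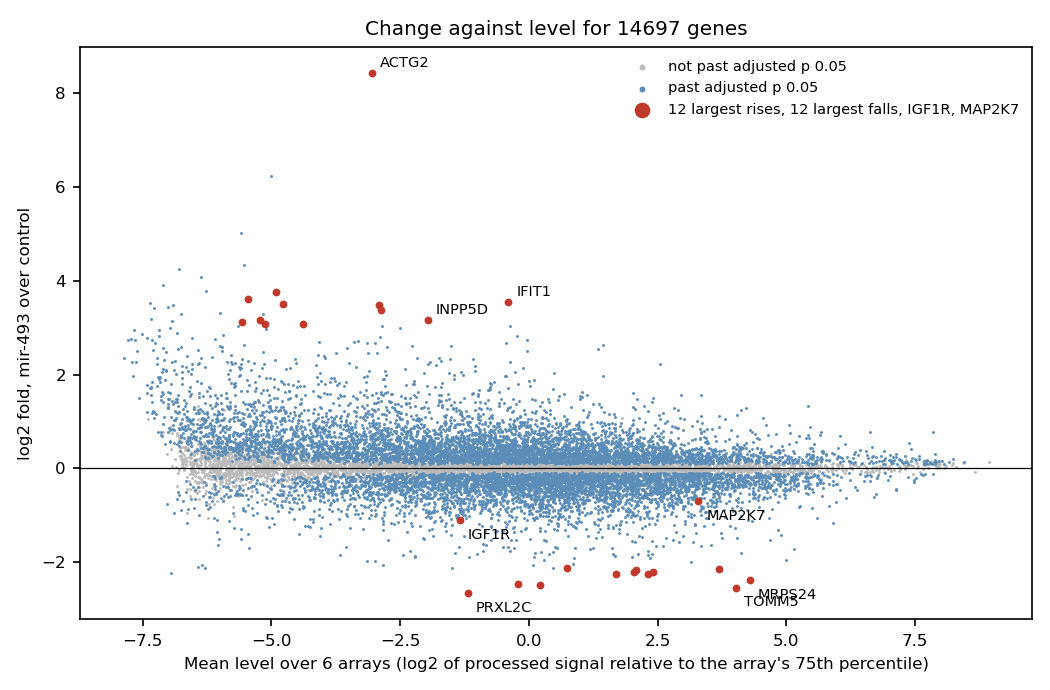
Log2 fold of mir-493 over control (vertical axis) against the mean level over the 6 arrays (horizontal axis, log2 of processed signal relative to the array's 75th percentile), 1 point for each of 14697 genes. Blue points passed an adjusted p of 0.05, grey points did not, and red points are the 12 largest rises, the 12 largest falls, IGF1R and MAP2K7; most of the largest rises sit among dim genes, with ACTG2 at 8.43, and the largest falls lie mostly at middle or high levels, with PRXL2C at -2.66.

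Among genes with at least 1 control array well above background, the largest rise was that of ACTG2, the gamma actin of smooth muscle, at a log2 fold of 8.43 (SE 0.27). Next came MB, which encodes myoglobin (3.76, SE 0.048), EDN2, which encodes endothelin 2 (3.62, SE 0.29), and IFIT1, an interferon-induced gene (3.55, SE 0.16). HRCT1 (3.51), TMT1A, a thiol methyltransferase (3.49), MYBPH, a myosin-binding protein (3.39), and INPP5D, an inositol phosphatase of blood cells (3.17), followed. The last of the 12 were TNNI2, a troponin of fast skeletal muscle (3.16), USHBP1 (3.11), PRSS57, a serine protease (3.09), and MYL7, a myosin light chain of the atrium (3.08). Most of these genes were dim in control cells. ACTG2, MB, EDN2, USHBP1 and PRSS57 were well above background on 1 of 3 control arrays, and HRCT1 and TNNI2 on 2 of 3, so the size of these rises is less certain than their direction. A 2nd probe for USHBP1 gave 1.51. With normexp background correction and quantile normalization all 12 rises were smaller and their order changed. ACTG2 was at 5.60, IFIT1 at 3.23, INPP5D at 2.68, TMT1A at 2.59 and MYBPH at 2.48. MB was then at 1.70, MYL7 at 1.64, HRCT1 at 1.63, TNNI2 at 1.29, EDN2 at 1.22, USHBP1 at 1.098 and PRSS57 at 1.09. Another 4 genes with rises of this size were not well above background on any control array, and only a bound on their rise can be given, which holds for the processed signal of the scanner software. PLA2G4D, a cytosolic phospholipase, was at least 31.1-fold higher after mir-493, PRR15L at least 13.6-fold, SORCS2 at least 11.1-fold, and BMF, which promotes apoptosis, at least 9.73-fold. Normexp gave smaller values than these bounds, with PLA2G4D at 6.01-fold, PRR15L at 3.43-fold, SORCS2 at 2.84-fold and BMF at 2.36-fold, so the size of these 4 rises depended on the background correction.

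The largest falls were those of PRXL2C, a peroxiredoxin-like gene (-2.66, SE 0.029), and TOMM5, a small subunit of the protein import channel in the outer mitochondrial membrane (-2.54, SE 0.036). CERCAM followed at -2.49 (SE 0.085), although its 2nd probe gave -0.52. DYNLRB1, a light chain of dynein, was at -2.47, MRPS24, a mitochondrial ribosomal protein, at -2.39, and RAB7A, a GTPase of late endosomes, at -2.26. B4GALT5, a galactosyltransferase, was at -2.25 and the calcium-binding S100A16 at -2.22. MAD2L1, a component of the spindle checkpoint, was at -2.21 (SE 0.041), and DPY30, a subunit of histone methyltransferase complexes, at -2.17. TPI1P2 was at -2.15. It is a pseudogene of TPI1, which encodes triosephosphate isomerase and was itself at -1.96, so the transcript that this probe measured is uncertain. TXNDC12, a thioredoxin-like protein of the endoplasmic reticulum, was at -2.13.

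IGF1R and MAP2K7 are reported targets of mir-493. Their adjusted p in limma was 2.46e-05 and 3.63e-05, and every mir-493 array lay below every control array for both. All 7 genes on the list of reported targets passed the threshold. The 5 that fell were MAD2L1, the Wnt antagonist DKK1 (-1.27), IGF1R, the cell cycle transcription factor E2F1 (-1.06) and MAP2K7, and the 2 that rose were FZD4 (0.35) and RHOC (0.40). The counts were the same when adjusted over the list alone. The list's median was -1.06, and camera gave an adjusted p of 0.0545 against the other genes and 0.585 with an estimated correlation. It passed with no filter on dim probes (adjusted p 0.0432), with the mean over a gene's probes (0.0496) and with trend and robust eBayes (0.0393). The published reports behind this list may include work on these arrays, so it is not independent evidence of its direction, and 5 of its genes also stand in other lists.

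Of the 22 p53 targets, 18 rose, 2 fell and 2 did not pass the test. TP53I3, an oxidoreductase induced by p53, was at 2.22, the cell cycle inhibitor CDKN1A at 1.80 (SE 0.050), SESN1 at 1.73, and BBC3, which encodes the pro-apoptotic protein PUMA, at 1.49. Camera gave an adjusted p of 9.97e-05 for the list, and an adjusted p of 0.585 with an estimated correlation. Of the 24 apoptosis regulators, 10 rose, 6 fell and 8 did not pass. The rises included BMF (a bound, above), BBC3 and the inhibitor of apoptosis BIRC3 (1.34). As a list they did not pass camera's test against other genes, with a median of 0.11 (-0.04 with median centring) and a camera adjusted p of 0.302. The counts of both lists were the same when adjusted over the list alone, and BBC3 and BAX belong to both.

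Of the 25 genes of S phase and replication, 21 fell, 1 rose and 3 did not pass. CDC45, a component of the replicative helicase, was at -1.83 (SE 0.050), E2F1 at -1.06, cyclin E2 (CCNE2) at -0.91, and RRM2, a subunit of ribonucleotide reductase, at -0.89. Camera gave an adjusted p of 7.1e-06, and an adjusted p of 0.429 with an estimated correlation. The list of G2/M and mitosis had a smaller median fall, -0.14 against -0.35, and this difference was not tested. Of its 23 genes tested, 13 fell, 1 rose and 9 did not pass. MAD2L1 was at -2.21, cyclin A2 (CCNA2) at -0.58, the spindle protein NUSAP1 at -0.54, and the kinetochore motor CENPE at -0.33. The camera adjusted p of this list was 0.0281, and it was 0.585 with an estimated correlation, 0.244 with quantile normalization (median -0.071), 0.194 with normexp (median -0.094), 0.0658 with the slide as a block, and 0.0512 without the array of mir-493 replicate 2. Median centring gave 0.00807 (median -0.283). The G2/M median was no farther out than those of random lists matched on level, of which a share of 0.312 lay as far out. The counts of both lists were the same when adjusted over the list alone.

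**Figure D2:**
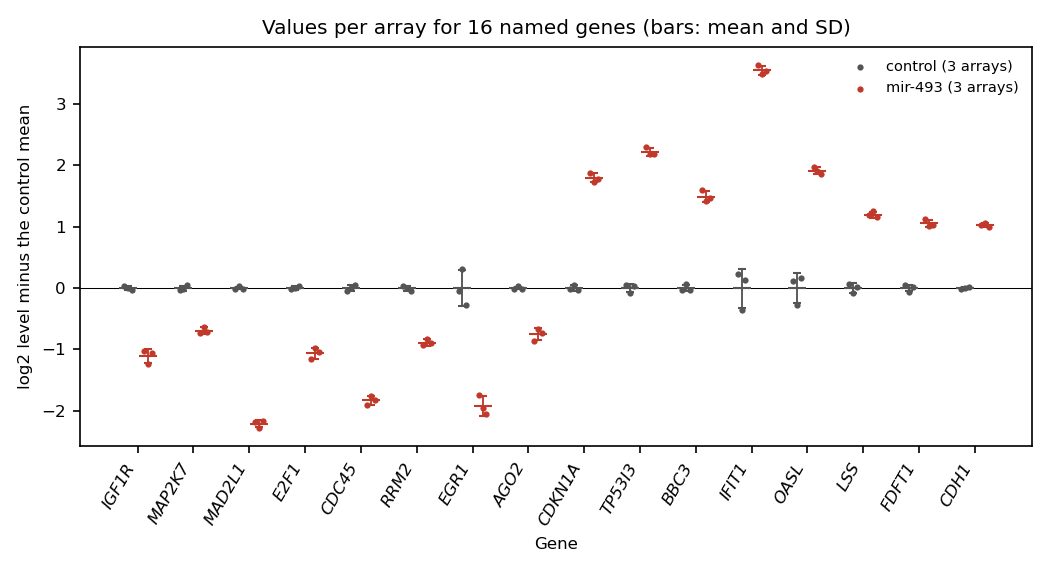
Log2 level of 16 named genes on each array minus the gene's control mean (vertical axis), with 3 control arrays in grey and 3 mir-493 arrays in red for each gene; horizontal marks are means and bars are SD. Every mir-493 array lies outside the range of the control arrays for each gene drawn, from MAD2L1 with a mean of -2.21 to IFIT1 with a mean of 3.55.

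Of the 20 interferon response genes tested, 16 rose, 1 fell and 3 did not pass. IFIT1 was at 3.55, OASL, an oligoadenylate synthetase-like protein, at 1.91 (SE 0.12), and IFIT2 at 1.91 (SE 0.12). IFI44 was not well above background on any control array and was at least 1.63-fold higher; with normexp it was 1.17-fold higher, below that bound. The list's median was 0.87, or 0.78 with IFI44 at its bound. Camera gave an adjusted p of 0.00016, and an adjusted p of 0.585 with an estimated correlation. The counts were the same when adjusted over the list alone.

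Of the 20 genes of cholesterol synthesis, 15 rose, 2 fell and 3 did not pass; adjusted over the list alone, 15 rose and 3 fell. The lanosterol synthase LSS was at 1.20, the squalene synthase FDFT1 at 1.06, and HMGCS1, an early enzyme of the mevalonate pathway, at 0.98. Camera gave an adjusted p of 0.0162, and an adjusted p of 0.585 with an estimated correlation. The list's median of 0.32 fell to 0.17 with median centring (adjusted p 0.00807). Of 18 genes of hypoxia and glycolysis, 9 rose, 4 fell and 5 did not pass, with a median of 0.19 (0.047 with median centring) and a camera adjusted p of 0.228. The aldolase ALDOC was at 1.90, the peptide hormone gene ADM at 1.06, NDRG1 at 0.97 and the mitophagy receptor BNIP3 at 0.86. The counts of the hypoxia list were the same when adjusted over the list alone.

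Members of 4 signalling lists moved in both directions, and none of these lists passed camera's threshold. Median centring moved the median of each by -0.145. In insulin and IGF signalling, 4 of 20 genes rose, 6 fell and 10 did not pass (median -0.046, adjusted p 0.361). Besides IGF1R, the falls included the kinases AKT2 (-0.78, with 2 other probes at 0.14 and -0.57), PIK3CA (-0.74) and AKT1 (-0.57). In the JNK pathway and AP-1 list, 3 of 17 rose, 8 fell and 6 did not pass (median -0.028, adjusted p 0.146). JUN, a subunit of AP-1, was at -0.82, the JNK phosphatase DUSP16 at -0.70 (-0.43 with normexp), MAP2K7 at -0.69 and DUSP10, another such phosphatase, at 0.59; the call of DUSP10 was lost with the slide as a block (adjusted p 0.137), with each of the 3 other scalings, and without mir-493 replicate 2 (0.0583) or replicate 3 (0.0634). Of 18 ERK feedback and immediate early genes, 12 fell, 4 rose and 2 did not pass (median -0.24, or -0.386 with median centring; adjusted p 0.0541). EGR1, an immediate early transcription factor, was at -1.92, PHLDA1 at 0.99, the receptor EPHA2 at -0.94, and SPRY4, a feedback inhibitor, at -0.92, with another SPRY4 probe at -0.18. The ERK list passed with no filter on dim probes (adjusted p 0.0432), with the mean over a gene's probes (0.0496), with trend and robust eBayes (0.0429), with the replicate number as a block (0.0443), without control replicate 3 (0.0397) and without mir-493 replicate 1 (0.0338), while an estimated correlation gave an adjusted p of 0.585. Of 14 Wnt/beta-catenin targets, 5 rose, 6 fell and 3 did not pass (median -0.062, adjusted p 0.465). DKK1 was at -1.27, the growth factor BMP4 at 0.90, the receptor EPHB2 at -0.79 and AXIN2, a feedback inhibitor of the pathway, at 0.51. The counts of these lists were the same when adjusted over the list alone.

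Of 20 epithelial genes, 11 rose, 7 fell and 2 did not pass (median 0.14, or -0.004 with median centring; camera adjusted p 0.343). VIL1, which encodes villin, was at least 2.93-fold higher, though normexp gave a smaller change than this bound (1.68-fold). The transcription factor ELF3 was at 1.43, E-cadherin (CDH1) at 1.03 and claudin 4 (CLDN4) at 0.93. Of 14 mesenchymal genes, 8 rose, 3 fell and 3 did not pass (median 0.46, adjusted p 0.302), and the median fell to 0.105 with normexp and 0.242 with quantile normalization. The matrix protein SPARC was at 1.95 (1.26 with normexp), CCN2 at 1.76, S100A4 at 1.28 and CCN1 at 1.25. Markers of other cell types moved too. Of 20 markers 13 were bright enough to be tested, of which 9 rose, 2 fell and 2 did not pass (median 0.39, adjusted p 0.155; 0.112 with normexp, 0.227 with quantile normalization and 0.245 with median centring), with the collagen gene COL1A1 at 1.59, the endothelial VWF at 1.57 (0.72 with normexp), and the globin gene HBB at least 1.48-fold higher. HBB lost its call with the slide as a block (adjusted p 0.0901) and with normexp, where it was 1.05-fold higher (0.225). The counts of these lists were the same when adjusted over the list alone.

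Of 18 genes of the unfolded protein and ATF4 response, 9 fell, 4 rose and 5 did not pass (median -0.14, or -0.282 with median centring; camera adjusted p 0.228). The stress-induced DDIT4 was at 1.12, while the transcription factor DDIT3 was at -0.60, SDF2L1 at -0.60 and HERPUD1 at -0.59; DDIT3 lost its call with the slide as a block (-0.43, adjusted p 0.062). Of 15 genes of the microRNA machinery, 7 fell, 4 rose and 4 did not pass (median -0.098, or -0.035 with normexp and -0.243 with median centring; adjusted p 0.253). AGO2, the Argonaute protein that can cut its targets, was at -0.75, the export factor XPO5 at -0.66 (with 2 other probes at -0.24 and -0.725), DICER1 at -0.59 and AGO4 at 0.46. AGO4 was at 0.25 with quantile normalization, and with normexp it was at 0.07 and lost its call (adjusted p 0.169). Counts were the same for these lists when adjusted over the list alone. Of 22 ribosomal protein genes, 12 rose, 0 fell and 10 did not pass in limma; adjusted over the list alone, 11 rose and 0 fell. RPL5 was at 0.26, RPL3 at 0.17 and RPL18 at 0.14; with normexp they were at 0.17, 0.08 and 0.03, and RPL3 (adjusted p 0.0806) and RPL18 (0.478) lost their calls. The list's camera adjusted p was 0.0545, and it was under 0.05 in 4 alternatives, from 0.019 with no filter on dim probes to 0.0496 with the mean over a gene's probes, and it was 0.585 with an estimated correlation. Their median of 0.10 lay within the shift between scalings and changed to -0.002 with normexp, 0 with quantile normalization and -0.042 with median centring.

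**Figure D3:**
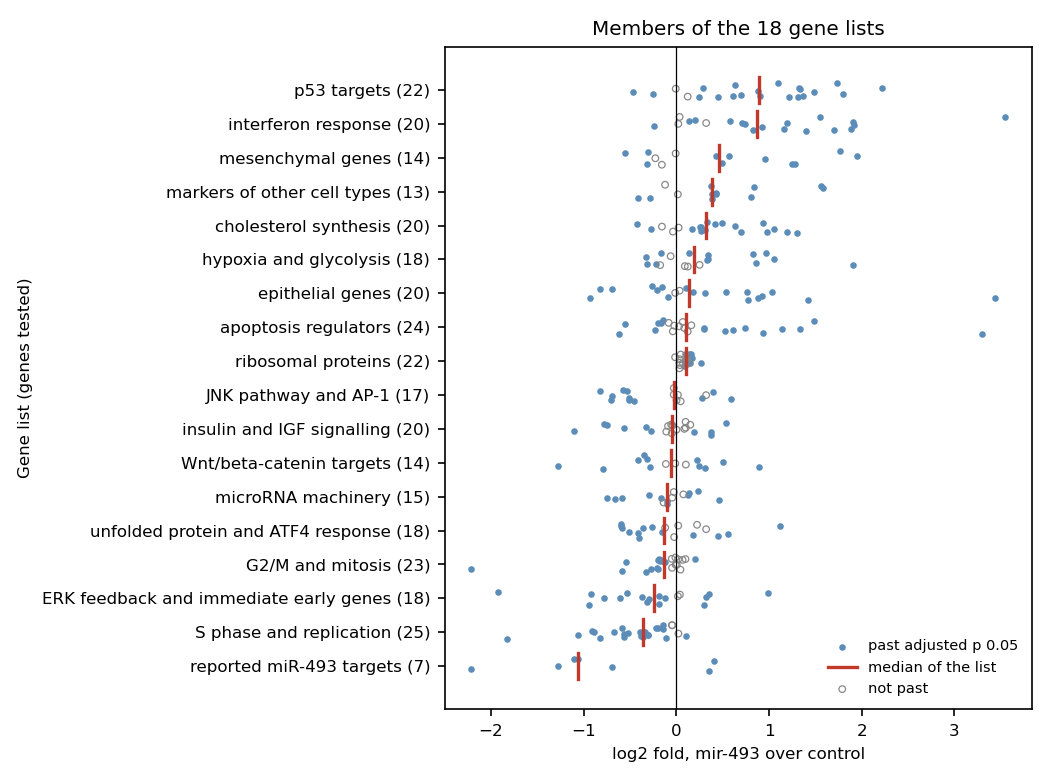
Log2 fold of mir-493 over control (horizontal axis) for each tested member of the 18 gene lists (vertical axis, number of genes tested in brackets), with filled points past an adjusted p of 0.05, open points not past it, and red bars at each list's median. The medians of p53 targets (0.90) and interferon response genes (0.87) lie farthest to the right and that of the reported mir-493 targets (-1.06) farthest to the left; the direction of the ribosomal protein list turns with normexp and median centring and its median is 0 with quantile normalization.

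Camera with its preset correlation passed 5 of the 18 lists, and with an estimated correlation it passed 0. Of the 18 lists, 1 then had an unadjusted p under 0.05. A call lost this way need not come from correlation among a list's genes. For the reported targets the estimated correlation was -0.114, below the preset 0.01, yet camera's unadjusted p rose from 0.0228 to 0.079. With an estimated correlation camera also takes its degrees of freedom from the few arrays, and with the preset one from the many genes. A call lost with an estimated correlation therefore does not show that a list was unshifted. Fry, which asks whether a list's genes move one way and not whether they differ from other genes, gave unadjusted p of 1.62e-05 for p53 targets, 1.72e-06 for S phase, 8.82e-06 for interferon response, 5.69e-05 for cholesterol synthesis and 0.000647 for G2/M. The slides were not balanced, since slide 1 held the 3 control arrays and mir-493 replicate 1 and slide 2 held mir-493 replicates 2 and 3. With the slide as a block, which leaves the comparison within slide 1 and its 1 mir-493 array, with the spread taken from all arrays, 8749 genes passed in limma (4825 higher and 3924 lower), and 8455 of these were also called, in the same direction, without the block. Within slide 1 IGF1R was at -1.02 and MAP2K7 at -0.74, and the list medians were 0.88 for p53 targets, 0.93 for interferon response, -0.37 for S phase, 0.40 for cholesterol synthesis and -0.12 for G2/M. Slide 2 held samples of 1 group only and gives no value of its own.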

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

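Signal also changed at probes without a gene name here, which enter only the count over probes and the adjustment of p above. Of 5150 such probes tested, 225 were at least 2-fold higher after mir-493 and 52 at least 2-fold lower at an adjusted p under 0.05 in limma. Among the 14697 named genes the counts were 797 and 310, a larger share in each direction. The genes of the unnamed probes were not worked out, and no explanation was tested.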

How the results depend on the processing

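Of 92 genes that the naming rule took, 84 kept their direction and their side of the threshold under every alternative run that could give their value. IGF1R stayed between -1.25 and -1.02. The number of genes past the threshold stayed within 1.5 times 10209 except under the stricter thresholds, with 1107 genes at 2-fold or more and 1742 with limma treat against 1.5-fold, which was chosen after seeing the data, as was slide 1 alone. Normexp with quantile normalization gave 301 genes at least 2-fold higher; the cause was not tested. Median centring gave 3665 genes higher and 499 at least 2-fold lower, because it moves every log2 fold by -0.145. Camera passed 8 lists without the filter on dim probes, 8 with the mean over a gene's probes and 8 with trend and robust eBayes; the cause was not tested. With an estimated correlation camera passed 0 lists (1 at an unadjusted p under 0.05). The medians stay the same by construction: 0.895 for p53 targets, -0.354 for S phase, -0.138 for G2/M, 0.873 for interferon response and 0.318 for cholesterol synthesis.

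The G2/M list was not past the threshold with normexp (median -0.094), quantile normalization (-0.071), the slide as a block (-0.124) or slide 1 alone (-0.124). Leaving out 1 array gave medians from -0.165 to -0.11, and the call was lost without mir-493 replicate 2. Its adjusted p ranged from 0.00807 to 0.585 over the alternatives. The cause was not tested, except that slide 1 alone has fewer arrays. The ribosomal protein list turned to -0.002 with normexp, 0 with quantile normalization and -0.042 with median centring, where RPL18 turned to -0.002. DUSP10 (adjusted p 0.00708 to 0.197), DDIT3 (0.00047 to 0.105), HBB (0.00518 to 0.225), AGO4 (0.000551 to 0.169), JUN (5.88e-05 to 0.0574), RPL3 and RPL18 lost their calls in at least 1 setting. Medians close to 0 changed sign for insulin and IGF signalling (up to 0.008), JNK and AP-1 (up to 0.03), Wnt targets (up to 0.018), epithelial genes (down to -0.004) and apoptosis regulators (down to -0.04).

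Equal replicate numbers did not pair the arrays: the deviations of arrays with the same number correlated at -0.0232, -0.0856 and 0.0143 across genes, and not every array correlated best with its own number. With the replicate number as a block, 9551 genes passed. The shift of genes with seed sites was not run. Dim genes set the limit of these arrays, as 213 of the genes tested had no control array well above background and 7 no mir-493 array, which leaves only a bound.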

Other observations

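In several gene families the members past the threshold moved mostly in one direction after mir-493, while others did not pass. None of these families passed camera with an estimated correlation, each at an adjusted p of 0.953. The families lie mostly outside the gene lists, apart from KRT8, KRT18 and KRT19 of the epithelial list and the RPL genes of the ribosomal list. Of the 36 keratin genes and pseudogenes (KRT) tested, 25 rose and 2 fell, with a median log2 fold of 0.54. KRT80 was at 2.82 (SE 0.12), KRT32 at 2.13 (SE 0.051) and KRT9 at 1.03. Of 12 small Cajal body RNAs (SCARNA), which guide the modification of spliceosomal RNAs, 11 rose and 0 fell in limma, with a median of 0.84, SCARNA16 at 1.63 and SCARNA9 at 1.47. Of 10 SNORA genes, small RNAs that guide pseudouridylation of ribosomal RNA, 8 rose and 0 fell, with a median of 0.36 and SNORA62 at 2.03. Of 15 host genes of small nucleolar RNAs (SNHG), 13 fell and 1 rose, with a median of -0.43, SNHG10 at -0.93 and SNHG1 at -0.66. These medians kept their sign with normexp, quantile normalization and median centring, but that of KRT fell to 0.146 with normexp and that of SNORA to 0.21 with median centring. Several keratin genes have close copies and pseudogenes, so which transcript a probe measured is uncertain. Whether the SCARNA and SNORA probes measured the small RNAs themselves or longer transcripts that contain them was not tested.

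Other families had smaller median shifts, and differences between families were not tested. Of 22 nucleoporin genes (NUP), 14 fell and 1 rose, with a median of -0.21 and NUP54 at -1.30. Of 14 ALG genes, which build the glycan for N-glycosylation, 10 fell and 0 rose, with a median of -0.25 and ALG3 at -1.19. Of 14 TIMM genes, which import proteins into mitochondria, 11 fell and 0 rose, with a median of -0.29 and TIMM8B at -0.54. These medians too kept their sign under the 3 other scalings, and median centring moved those of NUP and ALG to -0.357 and -0.391. Of 63 RPL genes and pseudogenes, 39 rose and 1 fell, with a median of 0.11 that turned to -0.033 with median centring.

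These 8 were the families past a camera adjusted p of 0.05 among 191 families of 10 or more genes with one symbol stem, a search made after the data were seen. The adjusted p was 0.00475 for KRT, 0.00475 for SNHG, 0.0056 for SCARNA, 0.0073 for NUP, 0.00967 for ALG, 0.0218 for RPL, 0.0376 for TIMM and 0.0428 for SNORA. With an estimated correlation camera passed 0 families, and 6 had an unadjusted p under 0.05. With the slide as a block 6 of them passed, all but RPL (adjusted p 0.0696) and TIMM (0.121). The tests of the families below, and those of slide, background and scaling, were chosen after the result was seen. The tests of level for the gene lists and of other splits were written before.

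Because dim genes rose more than bright ones, each of the 191 families was set against 10000 random lists of the same size matched on level, and the two-sided share of random lists with a median as far out was adjusted over all 191. The adjusted share was 0.00637 for KRT, 0.00637 for SCARNA and 0.00637 for SNHG, the smallest in the search. With the main scaling, the trend with level therefore does not account for these 3 shifts. The matched lists were not run with the other scalings. For KRT, whose median was 0.146 with normexp, the trend was thus not tested there. The RPL median lay close to that of its matched lists (0.11 against 0.10, adjusted share 0.875), so the trend with level may account for it. For TIMM (0.228), NUP (0.378), ALG (0.382) and SNORA (0.327) the adjusted share did not pass. The medians of their matched lists were -0.036, -0.031, -0.025 and 0.05, against -0.292, -0.212, -0.246 and 0.355 in the families. The trend with level thus predicted only a small part of these shifts. After adjustment, they could not be told apart from the scatter of random lists at the same level. The adjustment was added after the unadjusted shares of the 8 families had been seen, and that of TIMM was 0.0274 without it. Of the 191 families 6 passed an adjusted share of 0.05. The shares compare families with random lists of genes, whose members need not vary together. They speak only to the trend with level and to the scatter of such lists. Camera passed 8 families in the real split of the arrays and 8 in the highest of the other splits. As the other splits mix control and mir-493 arrays on each side, they keep part of the difference between the groups. Their counts thus cannot decide whether the families were called by chance.

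Rises of 2-fold or more outnumbered falls by a ratio of 2.571 and lay mostly among dim genes. Among the 3675 dimmest genes 504 rose and 46 fell by at least 2-fold, and among the 3674 brightest 32 rose and 92 fell. Higher background on the mir-493 arrays does not account for the ratio, which was 2.429 after the largest difference in negative-control signal between arrays of the groups (0.877 signal units) was subtracted from every mir-493 array; 775 of the 797 genes then remained at least 2-fold higher. The slide does not account for it either, with a ratio of 2.384 with slide as a block. Other scalings lowered it to as little as 1.234 with median centring, where it ranged from 1.159 to 1.252 when 1 array was left out. With only probes well above background on all 6 arrays the ratio was 1.874, and with no filter on dim probes it was 2.545. The stricter filter drops by design genes that were dim in one group. There were 213 genes with no control array well above background and 7 with no mir-493 array. Its lower ratio thus cannot show whether the filter makes the excess. Scaling may set much of the excess. Median centring was not combined with that stricter filter, so whether an excess remains under both was not tested. A response of the cells to mir-493 is a candidate explanation for any excess that remains, as a hypothesis that was not tested.

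For the p53 targets, interferon response and S phase lists, the trend with level was argued against by a largest share of 4e-04 among the 3 lists. The G2/M list, with a share of 0.312, lay inside the range of its matched lists. The slide was argued against by the shift within slide 1, where the median of each of the 3 lists was at least 14.21 times the largest median of 1 control array against the other controls; slide 1 holds 1 mir-493 array, so the spread is that of the controls. A response of the cells to mir-493 is a hypothesis that these arrays cannot decide. As each group received 1 oligonucleotide, a general response to the transfected RNA stays open too and was not tested. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold in limma, 1 of the 10 splits gave as many, with 10209 genes in the real split and 0 in the highest other (132 at an unadjusted p under 0.05). For lists past camera's threshold, 4 of the 10 splits gave as many, with 5 lists in the real split and 8 in the highest other. Every other split has arrays of both groups on each side. It thus keeps part of the difference between control and mir-493 and adds the rest to the spread. The counts of genes and lists in the other splits therefore do not show what arrays without a treatment difference would give.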
